A study of Mus musculus with 46 samples.

How the data were processed

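The series holds 46 samples, of which 18 are RNA-seq libraries of mouse liver and were analysed. The other 28, ChIP and ATAC samples by their labels, are not analysed here. Groups were taken from the labels, which give the genotype (WT, Heter, Homo), the age (young, elder) or the diet (control, CDAHFD) and a replicate number. They give no sex, strain or age in months. They do not say that the libraries come from separate animals, so p-values measure the spread between these samples, which may be technical. Per the labels' protocols, total RNA was taken from liver and made into libraries with a stranded kit, and poly-A purification is mentioned. Reads were paired ends of 150 bp. Per the submitters' processing notes, HISAT, HTSeq and DESeq2 were used and the build is GRCm38 (mm10), and no version is stated. Counting by strand is not given in the sources used here, so reads of overlapping or antisense genes and of near-identical family members (such as Mup, Cyp and Ugt1a genes) may be shared or lost.

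The authors deposited 1 table per library with counts and FPKM values for 21898 genes. Counts in the deposited files are whole numbers of reads per gene, not normalized. FPKM values in the deposited files equal the count divided by gene length and library total, per the file headers and the values, and were not used in any test. The 2 cohorts list 21899 genes between them, and a gene without values in 1 cohort is not reported there. Gene symbols, lengths and coordinates were taken from the files. Of 21795 gene identifiers matched to GENCODE M21, 21228 had the same name and 511 the same start and end. Totals per library ran from 14338099 to 18212901 counts over both cohorts. Mitochondrial genes took 5.53 to 9.11% of the counts in the ageing cohort and 5.80 to 8.66% in the diet cohort. Intervals and floors from counts cover counting error only. Replicates of a group differed by more than sampling noise in each pair (chi-square per degree of freedom 18.1 to 41.9), so none was counted as a duplicate.

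Counts were tested with edgeR 4.0.16 (quasi-likelihood test, robust fit) in R 4.3.3, with TMM normalization, filterByExpr, and Benjamini-Hochberg adjustment at 0.05. This gives each adjusted p of a gene in the text, and CPM are computed on TMM-scaled library sizes. The ageing fit had 6 groups, 12 libraries, 12881 genes after the filter and 6 residual degrees of freedom, with a common biological coefficient of variation of 0.163. The diet fit had genotype and diet as additive terms over 6 libraries, 12458 genes and 2 residual degrees of freedom (0.160), since each group has 1 library. TMM factors ran from 0.922 to 1.11 in the ageing cohort. In the diet cohort they were 0.818 to 0.845 for control and 1.17 to 1.25 for CDAHFD libraries. Standard errors are those of the log2 fold change. Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01, Benjamini-Hochberg within a comparison), and again with an estimated correlation, where a list had at least 5 tested members. There were 40 lists with 973 distinct genes, 945 of them in the files, covering liver metabolism, stress, inflammation, fibrosis, cell cycle and markers of the cell types that whole liver can hold. Genes of a list that passed when adjustment was made over the list's own members are called adjusted over the list alone. At the preset correlation, no list call in any of the 12 comparisons held with an estimated correlation. That second test rests on the residual degrees of freedom of the fit, so its power is limited, most so in the diet fit. In simulated counts of the ageing fit, with genes drawn independently, it still called a list raised 2-fold (camera adjusted p = 0.000393). There it called 0 of 39 unchanged lists. Calls may thus also be lost because members of real lists vary together more than the preset correlation assumes. The smallest adjusted p of the second test for CDAHFD was 0.329. A call lost in it does not show that a list was unchanged.

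Groups, tests, lists, alternatives and the rule for named genes were chosen before the data were examined. Named were Baz2b and up to 10 genes per direction with the largest fold change among called genes with an official symbol, mean CPM of at least 1 and groups that do not overlap. To these came up to 4 called members per list with the smallest p (2, with values only, where none was called). The text gives a selection of these. For single diet libraries, genes had CPM of at least 10 in 1 library and the same sign in Heter, and ratios had 1 CPM added. A ratio against a group with 1 to 3 counts is given with its 95% counting interval. List medians of single libraries were set against 10000 random lists matched on mean expression in 20 bins. Contrasts that share libraries were set beside 20 simulations of unchanged groups.

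The test was checked on simulated counts with 200 changed genes, drawn from genes with mean CPM of at least 5. Recovery of genes below that level was not checked. For the age comparison in WT it recovered 16.4% of genes changed by 1.5-fold, 64.2% by 2-fold and 95.5% by 4-fold. Recovery was 14.9, 79.1 and 95.5% for Homo against WT in elder livers, 1.49, 26.9 and 83.3% for the difference of the age change in Homo, and 34.3, 85.1 and 97.0% for CDAHFD. For Homo against WT in the diet cohort it was 20.9, 74.6 and 98.5%. In the order given, 9 of 126, 5 of 131, 4 of 78, 16 of 160 and 29 of 159 calls were false. The share of false calls was thus above the threshold of 0.05 in 4 of 5 simulations, most so in the diet cohort. Alternatives were DESeq2 1.42.0, its size factors in edgeR, no expression filter, only the groups compared, the replicate number as a block, another pseudocount (0.1 CPM), and each library left out in turn. Leaving out a library can leave a group with 1 sample, which is then assumed to vary like the other groups. The expression filter was run again on the remaining libraries. Its smallest group was then smaller, so genes with reads in fewer libraries could be tested. A call or value that moved may reflect this as well as the missing library. Fits of age over the 3 genotypes and of Homo over both ages, and the list medians with a library left out, were chosen after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.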

Results

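Gene expression was measured by RNA-seq in 18 mouse liver libraries of 3 Baz2b genotypes, labelled WT, Heter and Homo. Baz2b encodes a bromodomain protein of chromatin remodelling complexes, and the study's title asks whether acting on this protein lessens ageing and fibrosis of the liver. An ageing cohort held 12 libraries, 2 for each genotype in young and in elder mice. A diet cohort held 6 libraries, 1 for each genotype under a control diet and under CDAHFD. CDAHFD is the usual abbreviation of a choline-deficient, amino acid-defined high-fat diet, which is widely used to bring about steatohepatitis and fibrosis in mice. The total count per library ran from 14540392 to 17072466 in the ageing cohort and from 14338099 to 18212901 in the diet cohort. Between 14304 and 14751 genes had a read in an ageing library, and the 10 most abundant genes took 17.9 to 20.2% of its counts. In the diet cohort these ranges were 13711 to 15091 genes and 17.5 to 22.6%. Over the 12 ageing libraries the first principal component held 45.9% of the variance. It placed the 6 young libraries between -27.7 and -13.3 and the 6 elder libraries between 12.5 and 27.5.

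Baz2b mRNA was present at similar levels in the 3 genotypes of the ageing cohort, and its counts did not set the libraries labelled Homo apart from WT in the same direction at both ages. Young Homo libraries lay above young WT (27.8 to 28.9 against 23.3 to 25.4 CPM). Elder Homo libraries lay below elder WT (18.5 to 20.3 against 22.4 to 24.8 CPM). In young livers Baz2b stood at 24.4 ± 1.50 CPM in WT, 23.9 ± 1.15 CPM in Heter and 28.3 ± 0.801 CPM in the libraries labelled Homo (SD, n = 2 each). In elder livers these levels were 23.6 ± 1.68, 21.2 ± 1.54 and 19.4 ± 1.29 CPM. The difference between Homo and WT had a log2 fold change of 0.22 in young (adjusted p = 0.951) and -0.29 in elder livers (95% interval -0.57 to 0.00, adjusted p = 0.633). These adjusted p come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes. For Heter against WT the log2 fold changes were -0.03 (adjusted p = 0.995) and -0.16 (adjusted p = 0.937). With age Baz2b fell in the libraries labelled Homo (log2 fold change -0.55 ± 0.13 SE, adjusted p = 0.0397). That call was lost without any 1 of their 4 libraries (highest adjusted p 0.226). In WT the change was -0.05 and in Heter -0.18 (adjusted p = 0.887 and 0.612). The difference of the age change between Homo and WT was -0.50 (95% interval -0.91 to -0.09, adjusted p = 0.733). Under the control diet the single libraries held 19.5 CPM in WT, 10.7 in Heter and 8.11 in Homo, and under CDAHFD 12.8, 14.2 and 15.9 CPM. The labels do not say which part of the gene was altered, and a count over the whole gene can stay level where only part is deleted. These values do not check the labels. The gene (ENSMUSG00000026987) is listed on the minus strand of chromosome 2 from 59729707 to 60040183. The labels name GRCm38, yet only 511 of 21795 matched genes have the same start and end as in the GRCm38 annotation GENCODE M21. The build behind the printed coordinates is not settled.

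**Figure D1:**
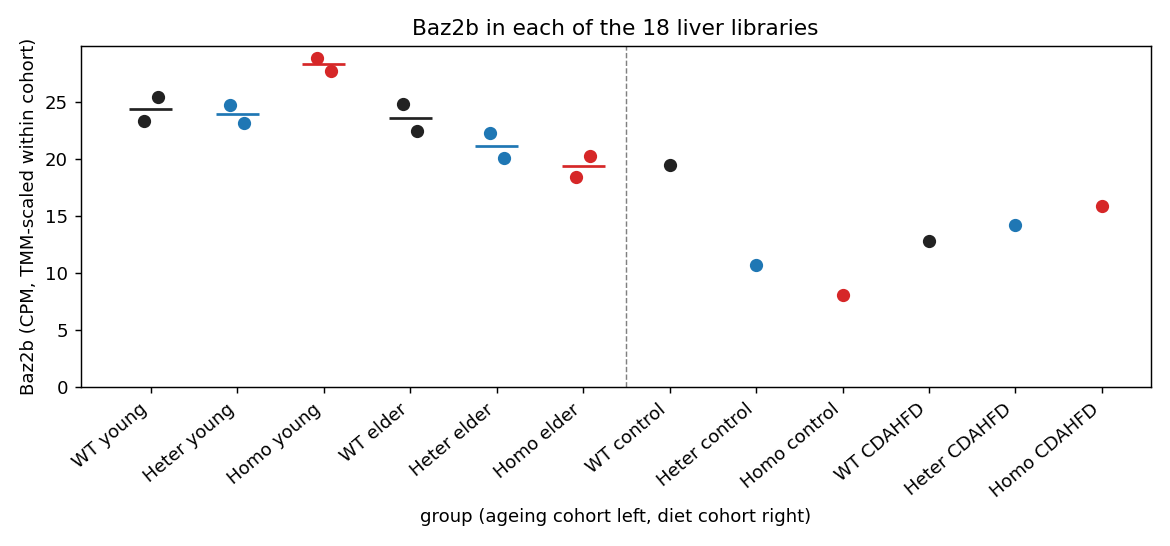
Baz2b expression in CPM for each of the 18 libraries, by genotype, with the ageing cohort and the diet cohort side by side. Each point is 1 library and each bar the mean of 2 libraries in the ageing cohort, where group means lie between 19.4 and 28.3 CPM.

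In WT livers, genes of fatty acid and triglyceride synthesis were lower in elder than in young mice (n = 2 each). Of 26 tested members 7 fell and 0 rose (13 fell adjusted over the list alone), with a median log2 fold change of -0.69. The list had camera adjusted p = 2.6e-08, and adjusted p = 0.513 with an estimated correlation. Scd1 (ENSMUSG00000037071, listed on chromosome 19 from 44382894 to 44396318), the desaturase that makes monounsaturated fatty acids, went from 14780 ± 806 to 65.3 ± 0.509 CPM (SD, n = 2 each; log2 fold change -7.82 ± 0.77 SE, adjusted p = 0.00621). Thrsp, an inducer of lipogenesis, Lpin1, a phosphatidate phosphatase, and Acacb, which makes malonyl-CoA, had log2 fold changes of -3.62, -3.19 and -1.58. Of 20 genes of gluconeogenesis and glycogen 6 fell (9 adjusted over the list alone), with a median of -0.67. This list had camera adjusted p = 3e-06, and adjusted p = 0.513 with an estimated correlation. Among them G6pc, the last enzyme of glucose release, went from 714 ± 276 to 44.8 ± 20.95 CPM (log2 fold change -3.99 ± 0.56, adjusted p = 0.0154). Tat, which breaks down tyrosine, had -2.30 ± 0.28 (adjusted p = 0.00381). Of 24 genes of amino acid breakdown and the urea cycle 4 fell (7 adjusted over the list alone), with a median of -0.36 (camera adjusted p = 4.3e-06, adjusted p = 0.592 with an estimated correlation). Ass1 and Cps1, both urea cycle enzymes, had -1.28 and -0.95. Hepatocyte markers, a list that shares Tat, Ass1 and Cps1 with these, had 6 of 20 members lower (6 adjusted over the list alone). Their median was -0.32 (camera adjusted p = 5.7e-05, adjusted p = 0.513 with an estimated correlation). The medians of the lipid, gluconeogenesis and amino acid lists ran from -0.89 to -0.61, from -0.91 to -0.38 and from -0.60 to -0.19 as each WT library was left out. Without 1 library the calls of Thrsp and Lpin1 were lost in each of 4 cases (highest adjusted p 0.167 and 0.140). Those of Ass1 and Cps1 were lost without either young library or elder library 1 (0.078 and 0.0996). That of Acacb was lost without either young library (0.0995) and that of G6pc without young library 1 or elder library 1 (0.0762).

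Genes that differ between male and female liver moved apart with age in WT. Of 16 male-high genes 2 fell and 0 rose (7 fell adjusted over the list alone), with a median log2 fold change of -1.75 (camera adjusted p = 1.5e-07, adjusted p = 0.513 with an estimated correlation). Of 12 female-high genes 2 rose and 0 fell (4 rose adjusted over the list alone), with a median of 3.03 (camera adjusted p = 0.00035, adjusted p = 0.514 with an estimated correlation). This median ran from 1.48 to 3.78 as each WT library was left out. Cyp2d9, a male-high cytochrome P450 whose reads near-identical family members may share, had -1.90 ± 0.34 (adjusted p = 0.0189, lost without any 1 of the 4 WT libraries, highest 0.112). Slc22a27, a female-high organic anion transporter, had 4.53 ± 0.65 (adjusted p = 0.00579). It ran from 3.69 to 6.74 as each library was left out, and its fold moved by over 1.5 times without either young library or elder library 2. Markers of monocyte-derived macrophages were higher in elder WT livers as a list, with 17 of 18 log2 fold changes above 0 and a median of 0.82. No member passed over all genes and 8 rose adjusted over the list alone (camera adjusted p = 5.7e-05, adjusted p = 0.260 with an estimated correlation). Targets of NF-kB and TNF signalling were higher as a list only, with a median of 0.55 (1 of 23 rose, 3 adjusted over the list alone, camera adjusted p = 0.00012, adjusted p = 0.247 with an estimated correlation), and their median ran from 0.33 to 0.77 as each WT library was left out. Erythroid genes had a median of -1.87 (1 of 9 fell, 5 adjusted over the list alone, camera adjusted p = 0.00085, adjusted p = 0.513 with an estimated correlation). The 12 genes of the mitochondrial genome had -0.30 (0 fell, 4 adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.514 with an estimated correlation), or -0.46 to -0.28 as each WT library was left out.

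Single genes that changed in elder WT livers came from several groups. Nebl, which encodes an actin-binding protein, rose from 0.834 ± 0.245 to 8.33 ± 1.75 CPM (log2 fold change 3.31 ± 0.33, adjusted p = 0.000561). Apoa4, a lipoprotein component, rose from 6.24 ± 1.91 to 94.0 ± 27.2 CPM (3.91 ± 0.52, adjusted p = 0.0130). This call was lost without either young library (highest adjusted p 0.116). Cyp27a1, an enzyme of bile acid synthesis, Ces2a, a carboxylesterase, Dnajb4, a co-chaperone, and Trp53inp1, a p53 target, fell (-0.85, -1.20, -1.01 and -1.07) and kept their calls with each WT library left out. In all, 424 of 12881 tested genes changed with age in WT, 177 higher and 247 lower (2494 at an unadjusted p under 0.05, and 781 by DESeq2). With 1 library left out the count was 63 without young library 1, 167 without young library 2, 160 without elder library 1 and 227 without elder library 2. Of 39 lists 17 were called at the preset correlation and 0 with an estimated one, and 10 kept their call with each WT library left out. The other 7 called lists had medians of -0.30 (bile acids and sterol export), -0.18 (nuclear genes of oxidative phosphorylation), -0.14 (heat shock), 0.29 (antigen presentation), 0.32 (interferon response), 0.36 (cholangiocyte markers) and 0.60 (cholesterol synthesis and uptake). Their adjusted p with an estimated correlation lay between 0.513 and 0.664. The cholesterol list went to 0.02 and turned in the test without elder library 1 (camera adjusted p = 0.905). Elder library 1 also decided oxidative phosphorylation (0.24 without it), and elder library 2 heat shock (0.37) and interferon genes (0.31). Antigen presentation was lost without young library 1 or elder library 2 (highest 0.21), cholangiocyte markers without young library 1 or elder library 1 (0.34), and bile acids without young library 2 or elder library 1 (0.083). Lists of fibrosis and extracellular matrix (-0.05), stellate cells (0.04), endothelial cells (0.00), T and NK cells (-0.08), ribosomal proteins (-0.07), chromatin remodelers (-0.05) and PPAR alpha targets (0.06) were not called. Neither were those of senescence (0.49), ER stress (0.44), the clock (-0.25), p53 targets (-0.18), NRF2 targets (-0.13), neutrophils (1.33), mesothelial cells (0.52) and adipocytes (-0.63, with a mean of 0.86).

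In Heter livers with age, the genes of cholesterol synthesis and uptake were higher in elder mice, with 25 of 25 log2 fold changes above 0 and a median of 1.03 (n = 2 each). No member passed over all genes and 15 rose adjusted over the list alone (camera adjusted p = 2.3e-12, adjusted p = 0.856 with an estimated correlation). B and plasma cell markers had a median of 0.80 (1 of 17 rose, 1 adjusted over the list alone, camera adjusted p = 2.5e-05, adjusted p = 0.283 with an estimated correlation). Jchain, the joining chain of secreted antibodies, rose from 0.588 ± 0.266 to 9.09 ± 5.99 CPM (3.94 ± 0.58, adjusted p = 0.00717). Its call was lost without young library 1 or elder library 1 (highest 0.0829), and without elder library 1 its log2 fold change was 3.04. Dusp1, a phosphatase that switches off MAP kinases, fell from 74.1 ± 11.6 to 13.2 ± 1.05 CPM (-2.49 ± 0.23, adjusted p = 0.000798). Slc25a25, a mitochondrial carrier, fell too (-2.79 ± 0.28, adjusted p = 0.00152). G6pc fell from 961 ± 252 to 48.7 ± 16.3 CPM (-4.30 ± 0.57, adjusted p = 0.0256). Its call was lost without any 1 of the 4 Heter libraries (highest 0.166). In all, 84 of 12881 genes changed, 41 higher and 43 lower (1743 at an unadjusted p under 0.05, and 384 by DESeq2). With young library 1, young library 2, elder library 1 or elder library 2 left out, the counts were 53, 47, 26 and 62. Male-high genes (-1.16), mitochondrial genes (-0.41) and cell cycle genes (-0.40, or -0.43 to -0.23 as each Heter library was left out) were lower as lists. Female-high genes were higher (2.32, or 1.36 with genes at 0 in a group set to their bound). Each of these 4 lists had adjusted p = 0.856 with an estimated correlation, and the male-high and female-high medians ran from -1.76 to -0.75 and from 0.43 to 3.67 as each Heter library was left out. Interferon genes had a median of -0.38 (camera adjusted p = 2.4e-05, adjusted p = 0.856 with an estimated correlation), and the call was lost without young library 1 (0.26).

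In the libraries labelled Homo, endothelial markers and heat shock genes were lower in elder than in young mice (n = 2 each). Of 21 endothelial markers 10 fell and 0 rose (16 fell adjusted over the list alone), with a median of -0.59 (camera adjusted p = 4.6e-09, adjusted p = 0.444 with an estimated correlation). Lyve1, a hyaluronan receptor of sinusoidal and lymphatic endothelium, fell from 12.9 ± 2.30 to 1.55 ± 0.926 CPM (-3.04 ± 0.48, adjusted p = 0.00875). The call of Lyve1 was lost without elder library 2 (0.0589), and its log2 fold change was -3.83 without elder library 1. Gpr182, Dnase1l3 and Stab1, also of sinusoidal endothelium, had -0.86, -0.66 and -0.64. The calls of Gpr182 and Stab1 were lost without young library 1 or either elder library, and that of Dnase1l3 without any 1 of the 4 libraries (highest adjusted p 0.132, 0.165 and 0.136). Of 18 heat shock genes 9 fell (13 adjusted over the list alone, median -0.78, camera adjusted p = 3.9e-10, adjusted p = 0.444 with an estimated correlation). Among them were the chaperones Dnajb1 (-1.34, lost without either elder library, highest adjusted p 0.0683) and Hspa8 (-0.94, lost without young library 1 or either elder library, 0.0607). Dnajb9, a chaperone of the endoplasmic reticulum, fell from 227 ± 0.758 to 53.6 ± 0.0126 CPM (-2.08 ± 0.22, adjusted p = 0.0026). Antigen presentation genes were higher as a list (3 of 22 rose, 12 adjusted over the list alone, median 0.57, camera adjusted p = 3.3e-05, adjusted p = 0.444 with an estimated correlation). So were macrophage markers (3 of 18 rose, 5 adjusted over the list alone, median 0.51, camera adjusted p = 0.0035, adjusted p = 0.444 with an estimated correlation). Mmp12, a macrophage elastase, went from 0.196 ± 0.0823 to 7.04 ± 6.76 CPM (5.10 ± 1.00, adjusted p = 0.0242, and 3.47 to 5.84 as each library was left out). Its call was lost without either young library or elder library 1 (highest 0.143). Male-high genes had a median of -1.91, female-high genes 2.43, mitochondrial genes -0.60 and ER stress genes -0.45 (adjusted p = 0.477, 0.557, 0.444 and 0.726 with an estimated correlation). As each library was left out, the medians of macrophage markers, female-high genes and mitochondrial genes ran from 0.23 to 0.85, from 2.29 to 5.16 and from -0.95 to -0.38. In all, 513 of 12881 genes changed, 267 higher and 246 lower (2770 at an unadjusted p under 0.05, and 860 by DESeq2). With young library 1, young library 2, elder library 1 or elder library 2 left out, the counts were 171, 145, 85 and 95.

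Across genotypes, genes that changed with age in 2 genotypes moved the same way. WT and the libraries labelled Homo shared 167 called genes, 76 higher and 91 lower in both, where independent lists would share 3.67 and 4.72. WT and Heter shared 62 (28 higher and 34 lower, against 0.563 and 0.825), and Heter and Homo shared 50 (27 higher and 23 lower, against 0.850 and 0.821). The age changes of these pairs rest on separate libraries, and their correlations across genes were 0.616, 0.562 and 0.558, with genes not being independent replicates. The 3 contrasts share 1 estimate of the spread and 1 filter. The same genes may be easier to call in each, so the numbers for independent lists are a rough reference. Any other difference common to the elder libraries would also give a shared direction. Nebl rose in each genotype (3.31, 2.55 and 4.34 in WT, Heter and Homo) and kept its call with each library left out. In a fit of age over the 3 genotypes together, chosen after the data were seen, 2348 of 12881 genes changed, 1181 higher and 1167 lower (4157 at an unadjusted p under 0.05).

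**Figure D2:**
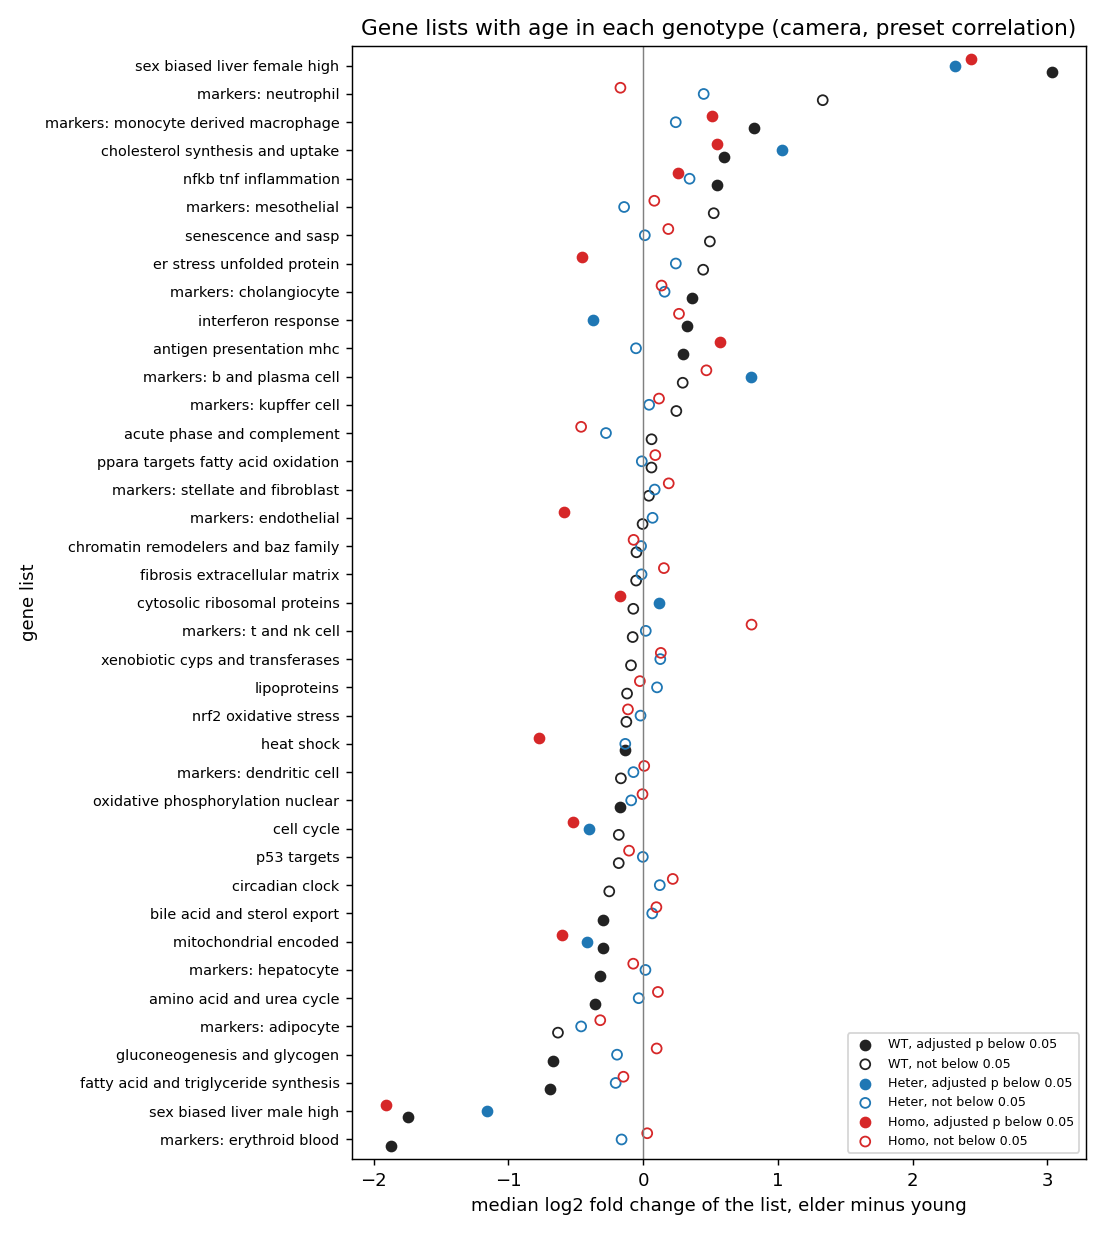
Median log2 fold change of gene lists, elder minus young, for WT, Heter and Homo, with 1 point per list and genotype and filled points where camera gave an adjusted p under 0.05 at the preset correlation. Male-high genes lie at -1.75, -1.16 and -1.91 and endothelial markers at -0.59 in Homo.

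**Figure D3:**
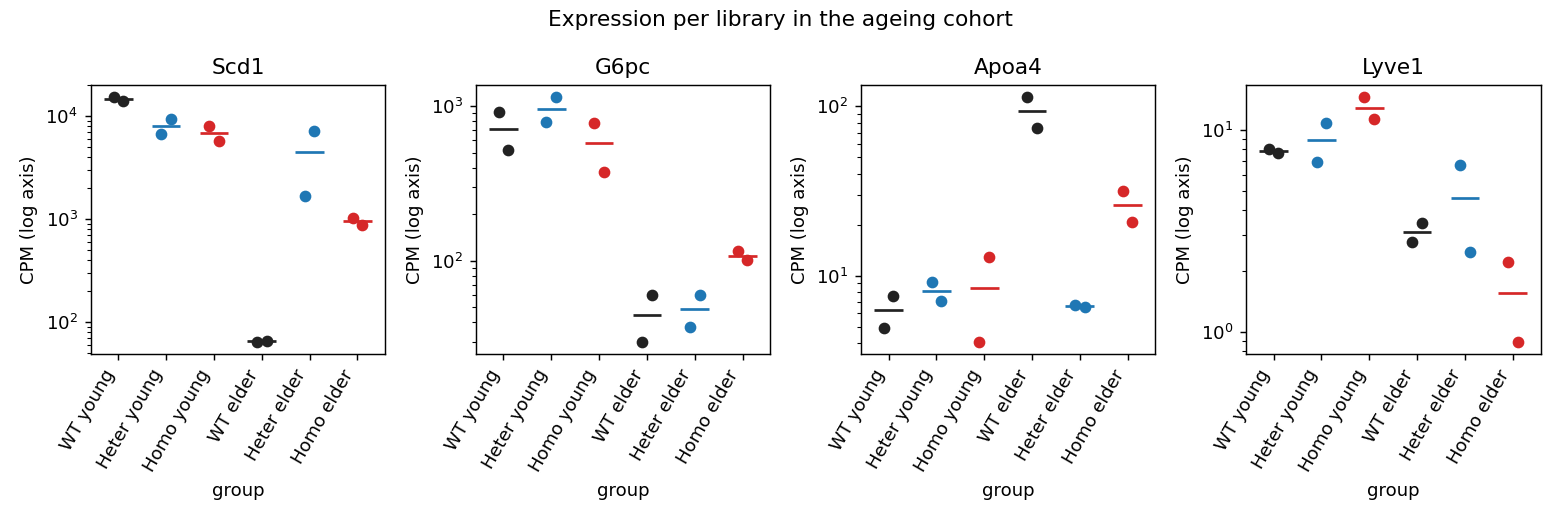
Expression of Scd1, G6pc, Apoa4 and Lyve1 in CPM on a log axis, with 1 point per library in the 6 groups of the ageing cohort. Scd1 stands at 64.9 and 65.6 CPM in the WT elder libraries and between 884 and 7270 CPM in the elder libraries of the other genotypes.

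Among elder livers, the libraries labelled Homo had lower endothelial markers than WT (n = 2 each). Homo is given as the label states it, because Baz2b counts over the whole gene cannot check it. The median over 21 markers was -0.46, with 20 of the 21 log2 fold changes below 0 (camera adjusted p = 6.6e-11, adjusted p = 0.716 with an estimated correlation). No marker passed over all genes and 9 were lower adjusted over the list alone. Kdr and Flt1, receptors of vascular endothelial growth factor, had -0.59 ± 0.14 and -0.74 ± 0.17 (adjusted p = 0.302 for both). The list kept its call with each of the 4 libraries left out. ER stress genes had a median of -0.51 (0 called, 13 lower adjusted over the list alone, camera adjusted p = 3.5e-06, adjusted p = 0.716 with an estimated correlation), a call lost without WT elder library 1 (0.13), with medians from -0.86 to -0.22 as each library was left out. Amino acid and urea cycle genes had 0.39 (0 called, 3 higher adjusted over the list alone, camera adjusted p = 3.2e-08, adjusted p = 0.716 with an estimated correlation), a call lost without Homo elder library 2 (0.082), with medians from 0.17 to 0.63. Of 11 lists called, 1 kept its call with each library left out. Hepatocyte markers had 0.12 (2 higher adjusted over the list alone, camera adjusted p = 0.033, adjusted p = 0.896 with an estimated correlation), lost without WT elder library 1 or Homo elder library 2 (highest 0.943). T and NK cell markers had 0.38 (0 adjusted over the list alone) and erythroid genes 1.37 (1 higher and 1 lower). Both had camera adjusted p = 0.028 and adjusted p = 0.716 with an estimated correlation. Both were lost without WT elder library 2 or Homo elder library 2 (0.267 and 0.299). Scd1 stood at 955 ± 101 CPM against 65.3 ± 0.509 in WT (3.87, adjusted p = 0.302). Fatty acid and triglyceride synthesis as a list had only 0.15 (1 higher adjusted over the list alone, camera adjusted p = 0.0454, adjusted p = 0.937 with an estimated correlation), lost without WT elder library 2 or either Homo elder library (highest 0.364). By edgeR 0 of 12881 genes changed (1030 at an unadjusted p under 0.05, and 48 by DESeq2), the smallest adjusted p being 0.0650, and without WT elder library 2 the count was 49.

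Heter elder livers differed from WT elder livers in 4 genes by edgeR (780 at an unadjusted p under 0.05, and 38 by DESeq2). Ugt1a5, a glucuronosyltransferase whose exons overlap other genes of its cluster, rose from 7.83 ± 2.07 to 44.0 ± 12.4 CPM (2.49 ± 0.27, adjusted p = 0.0174). Its call was lost without either WT elder library (highest 0.101). Mgll, the lipase of monoglycerides, fell from 237 ± 3.40 to 127 ± 2.19 CPM (-0.91 ± 0.13, adjusted p = 0.0253). So did Fam102a (-0.87, adjusted p = 0.0253) and Lect2, a secreted hepatokine (-0.85, adjusted p = 0.0372). The calls of Mgll and Fam102a were lost without any 1 of the 4 libraries (highest adjusted p 0.270 and 0.251), and that of Lect2 without either WT library or Heter elder library 2 (0.444). As lists, genes of fatty acid and triglyceride synthesis were higher (median 0.49, 0 called, 2 higher adjusted over the list alone, camera adjusted p = 1.1e-06, adjusted p = 0.563 with an estimated correlation). PPAR alpha targets (-0.29, 4 lower adjusted over the list alone, adjusted p = 0.569 with an estimated correlation) and interferon genes (-0.41, 0 adjusted over the list alone, adjusted p = 0.563 with an estimated correlation) were lower. As each library was left out, these medians ran from 0.31 to 0.64, from -0.43 to -0.12 and from -0.60 to -0.18. Hepatocyte markers had 0.24 (3 higher adjusted over the list alone, camera adjusted p = 1.3e-05) and erythroid genes 1.66 (5 higher, 3.2e-06). Both had adjusted p = 0.563 with an estimated correlation and kept their calls, with medians from 0.08 to 0.37 and from 1.08 to 1.64. B and plasma cell markers (0.68, adjusted p = 0.563 with an estimated correlation) and endothelial markers (0.08, 0.789) were called as well. These calls were lost without WT elder library 2 (0.164), and the endothelial one without Heter elder library 1 too (highest 0.518). Scd1 stood at 4477 ± 3950 CPM in Heter elder livers against 65.3 ± 0.509 in WT (6.10, adjusted p = 0.122), and Apoa4 at 6.61 ± 0.118 against 94.0 ± 27.2 CPM (-3.83, adjusted p = 0.168).

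In young livers the genotypes differed little by single genes. Id2, an inhibitor of helix-loop-helix factors, was the 1 gene called in Heter against WT (1.30 ± 0.17, adjusted p = 0.0303, 602 at an unadjusted p under 0.05, and 1 by DESeq2). Its call was lost without any 1 of the 4 libraries (highest 0.703). By edgeR 0 genes changed in the libraries labelled Homo against WT (635 at an unadjusted p under 0.05, and 7 by DESeq2). Genes of fatty acid and triglyceride synthesis had a median of -0.71 in young Homo against young WT (25 of 26 below 0, 2 lower adjusted over the list alone, camera adjusted p = 1.3e-09, adjusted p = 0.683 with an estimated correlation). Other cell-type lists called there were stellate cells (-0.28), neutrophils (0.70) and erythroid genes (-0.50). Each had adjusted p = 0.683 with an estimated correlation and lost its call with a library left out (highest 0.174, 0.433 and 0.231). Gpam, which starts triglyceride assembly, had -0.91 there (adjusted p = 0.764). In young Heter, PPAR alpha targets had a median of -0.18 (45 of 50 below 0, 0 adjusted over the list alone, camera adjusted p = 3.7e-06, adjusted p = 0.743 with an estimated correlation), or -0.27 to -0.09 as each library was left out. Lists of hepatocytes (-0.14), macrophages (0.31), cholangiocytes (0.16) and mesothelial cells (0.32) were also called in young Heter. None was called with an estimated correlation, and each lost its call with a library left out (highest 0.292, 0.136, 0.884 and 0.485). Of 15 and 18 lists called in these comparisons, 1 in each kept its call with each library left out.

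The age changes themselves differed between genotypes in 13 lists each for Homo and Heter at the preset correlation, and in 0 with an estimated one. Against WT, the age change in the libraries labelled Homo was higher for fatty acid and triglyceride synthesis (median difference 0.92, 1 higher adjusted over the list alone), amino acid and urea cycle genes (0.63, 2 higher adjusted over the list alone) and gluconeogenesis (0.51, 0 adjusted over the list alone). It was lower for ER stress genes (-0.87, 10 lower adjusted over the list alone) and endothelial markers (-0.58, 10 lower adjusted over the list alone). These 5 lists kept their calls with each of 8 libraries left out, although the ER stress median ran from -1.15 to -0.38 and the amino acid median from 0.35 to 0.79. Each had adjusted p = 0.599 with an estimated correlation. In Heter the age change was higher for fatty acid and triglyceride synthesis (0.76, 4 higher adjusted over the list alone). It was lower for interferon genes (-0.75, 2 lower adjusted over the list alone), and both lists had adjusted p = 0.441 with an estimated correlation. Their medians ran from 0.47 to 1.16 and from -0.98 to -0.47 as each library was left out. Cell-type lists differed in Heter as well, with hepatocyte markers at 0.30, erythroid genes at 1.49, macrophage markers at -0.60 and cholangiocyte markers at -0.24. The calls of the macrophage and cholangiocyte lists were lost with a library left out. By edgeR 0 genes had a different age change in Homo (802 at an unadjusted p under 0.05, and 18 by DESeq2), against 30 without WT elder library 2. Ugt1a5 was the 1 gene called in Heter (3.47 ± 0.37, adjusted p = 0.0142, 751 at an unadjusted p under 0.05). It was not called by DESeq2, which called 32 genes, nor without WT young library 2 or WT elder library 1 (highest 0.113).

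Whether the genotype moved expression against the direction of age was compared across genes in libraries that do not overlap. The age changes in Heter and the differences between Homo and WT in elder livers had r = -0.0529 and rho = -0.0416 over 12881 genes, where simulated unchanged groups gave -0.0394 to 0.0309. As each library was left out, r ran from -0.0782 to -0.00995, which reaches into that range. Over genes with mean CPM of at least 10 it was -0.0984. The simulations drew each gene independently, so their range is too narrow for genes that vary together. An r outside that range therefore does not exclude chance. Of the 84 genes called with age in Heter, 61.9% had the opposite sign in Homo elder against WT elder, and 50.9% of all genes did. Differences between Homo and WT in young and in elder livers had r = 0.0560 and rho = 0.0317, where simulated unchanged groups gave -0.0195 to 0.0486. That r was -0.0362 over genes with mean CPM of at least 10, and -0.0328 to 0.0605 as each library was left out, so its direction is not firm. Against the WT age change, whose WT elder libraries also enter the genotype contrasts, r was -0.367 for Homo elder and -0.388 for Heter elder, and simulated unchanged groups gave -0.489 on average. The covariances were -0.108 and -0.116, and the simulated ones -0.0711 and -0.0719. The simulations gave each group the same spread, whereas the WT elder libraries differed most from each other (chi-square per degree of freedom 41.9). A wider spread there would by itself make these covariances more negative, so the excess decides nothing. Homo elder and Heter elder, each against the same WT elder libraries, had r = 0.460 (0.491 simulated) and a covariance of 0.0882 (0.0710 simulated), and part of this may come from the shared controls.

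CDAHFD livers held far more macrophage, matrix and cell cycle transcripts than control livers, averaged over the 3 genotypes (n = 3 libraries each). Each of 19 tested markers of monocyte-derived macrophages rose (19 adjusted over the list alone), with a median log2 fold change of 4.94 (camera adjusted p = 3.9e-12, adjusted p = 0.329 with an estimated correlation). Mmp12 (ENSMUSG00000049723, listed on chromosome 9 from 7344381 to 7369499) went from 0.102 ± 0.0395 to 381 ± 40.2 CPM (11.75 ± 0.21, adjusted p = 3.7e-07). Trem2, a lipid receptor of macrophages, went from 0.285 ± 0.121 to 51.3 ± 7.09 CPM (7.47 ± 0.21, adjusted p = 1.6e-06). Gpnmb, a glycoprotein of lipid-laden macrophages, was 8315 times as abundant as in the control libraries, which held 2 counts of it in all (95% counting interval 2302 to 68666). Its log2 fold change ran from 12.35 to 15.71 as each library was left out. Of 52 genes of fibrosis and extracellular matrix 43 rose and 1 fell (43 and 2 adjusted over the list alone, median 2.09, camera adjusted p = 1.3e-11, adjusted p = 0.431 with an estimated correlation). Col4a1, a basement membrane collagen, rose from 26.5 ± 3.72 to 111 ± 7.80 CPM (2.07 ± 0.12, adjusted p = 2.1e-05). Lum, a collagen-binding proteoglycan, rose from 5.53 ± 0.858 to 35.8 ± 3.70 CPM. Of 40 cell cycle genes 34 rose and 0 fell (34 adjusted over the list alone, median 1.91, camera adjusted p = 3.8e-10, adjusted p = 0.329 with an estimated correlation). Mki67, a proliferation marker, had 3.53 ± 0.32 (adjusted p = 0.000141).

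Markers of other cell types rose with the macrophage list, while endothelial and hepatocyte markers fell. In the counts that follow, alone means adjusted over the list alone. T and NK cell markers (15 of 17 rose and 1 fell, 16 and 1 alone, median 2.63) and cholangiocyte markers (16 of 18, 16 alone, 2.38) were higher. So were dendritic cell markers (7 of 12, 1 fell, 8 and 1 alone, 2.21), neutrophil markers (4 of 7, 4 alone, 1.84) and stellate cell markers (13 of 22, 2 fell, 13 and 2 alone, 1.00). These 5 lists had adjusted p between 0.329 and 0.431 with an estimated correlation. The calls of the neutrophil markers Mmp9 and S100a8 were lost without 4 and 1 of the 6 libraries. Their log2 fold changes ran from 1.39 to 2.31 and from 2.29 to 4.84 as each library was left out. Il7r, a cytokine receptor of lymphocytes, had 5.91 (5.51 to 7.11 as each library was left out), and Ehf, an epithelial transcription factor, 3.37. Antigen presentation genes (18 of 22 rose, 18 alone, median 1.18) and interferon genes (30 of 42, 1 fell, 31 and 1 alone, 1.43) rose as well, with adjusted p = 0.403 and 0.488 with an estimated correlation. So did NF-kB and TNF targets (20 of 25, 1 fell, 21 and 1 alone, 1.60) and senescence and secretory genes (17 of 29, 18 alone, 1.44), both with adjusted p = 0.329 with an estimated correlation. Cd74, the invariant chain of class II molecules, went from 14.3 ± 3.75 to 238 ± 50.3 CPM. Of 21 endothelial markers 17 fell and 2 rose (17 and 2 adjusted over the list alone, median -1.99, camera adjusted p = 7.5e-07, adjusted p = 0.329 with an estimated correlation). Kdr went from 18.3 ± 1.25 to 1.76 ± 0.270 CPM (-3.38 ± 0.19). Of 20 hepatocyte markers 15 fell (16 and 1 higher adjusted over the list alone, median -0.85, camera adjusted p = 5.6e-06, adjusted p = 0.332 with an estimated correlation). Kupffer cell markers (10 rose and 4 fell of 17, median 1.13) and B and plasma cell markers (2 rose of 7, median 0.86) were not called as lists. The pancreatic acinar, adipocyte and mesothelial lists had fewer than 5 members to test, and Cela1, an elastase of the first, had -2.10.

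Many lists of metabolic genes were lower in CDAHFD livers, where alone again means adjusted over the list alone. Hepatocyte markers fell in the same whole-liver libraries. A lower share of hepatocytes may therefore account for part of these falls, which was not tested. Of 46 nuclear genes of oxidative phosphorylation 43 fell and 0 rose (45 alone, median -0.55, camera adjusted p = 1.3e-11, adjusted p = 0.329 with an estimated correlation). All 16 tested male-high genes fell (16 alone, median -3.03) and all 9 female-high genes rose (9 alone, median 4.49), with adjusted p = 0.329 and 0.403 with an estimated correlation. Hsd3b5, a male-high steroid reductase, went from 318 ± 64.6 to 0.590 ± 0.197 CPM (-9.01 ± 0.24), and Cyp2a4, a female-high cytochrome P450 with a near-identical paralog, had 7.38. Genes of xenobiotic metabolism (17 of 32 fell and 5 rose, 17 and 8 alone, median -0.59) had adjusted p = 0.329 with an estimated correlation. Cyp2c29 among them went from 1250 ± 149 to 28.7 ± 7.59 CPM. Amino acid and urea cycle genes fell (16 of 24, 1 rose, 18 and 1 alone, median -0.68, adjusted p = 0.403 with an estimated correlation). Fatty acid and triglyceride synthesis (13 of 25, 2 rose, 13 and 2 alone, -0.73), cholesterol synthesis (14 of 25, 1 rose, 15 and 1 alone, -0.63), bile acids (11 of 21, 3 rose, 11 and 3 alone, -0.60) and gluconeogenesis (8 of 20, 1 rose, 8 and 1 alone, -0.52) were lower as lists, each with adjusted p = 0.431 with an estimated correlation. Scd2, a desaturase, and Ppargc1a, a coactivator of gluconeogenesis, were among those that rose (2.73 and 1.05). ER stress genes (18 of 28, 2 rose, 19 and 2 alone, -0.72) and heat shock genes (12 of 18, 13 alone, -0.86) fell too. So did mitochondrial genes (9 of 12, 9 alone, -0.72). Erythroid genes (3 of 7 fell, 3 alone, -1.20) and ribosomal protein genes (16 of 53 fell, 8 alone, -0.23) were lower as lists, with most members not called. These 5 lists had adjusted p of 0.431 to 0.522 with an estimated correlation. The calls of 3 erythroid members, Fech, Alas2 and Tfrc, were lost without 5, 4 and 4 of the 6 libraries (highest adjusted p 0.108, 0.134 and 0.173). Targets of p53 were higher as a list (10 of 22 rose, 10 alone, 0.51, adjusted p = 0.329 with an estimated correlation). Of 23 lipoprotein genes 12 fell and 5 rose (14 and 5 alone), with a median of -0.44 and a mean of 0.07 (camera adjusted p = 0.0400, adjusted p = 0.431 with an estimated correlation). Cd36, a fatty acid transporter, and Lpl, a lipase made by macrophages as well, were among those that rose (4.08 and 3.54). Lists of PPAR alpha targets (18 rose and 9 fell of 50), acute phase genes (5 and 10 of 30), NRF2 targets (8 and 7 of 22), clock genes (6 and 6 of 19) and chromatin remodelers (2 and 1 of 20) were not called.

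By edgeR 5400 of 12458 genes changed with CDAHFD, 2961 higher and 2439 lower (4693 by DESeq2). The fit has 2 residual degrees of freedom, and any interaction of genotype and diet enters its error. Without the WT control, Heter control, WT CDAHFD or Heter CDAHFD library the counts were 3578, 3347, 3599 and 3312. They were 5391 and 5241 without the Homo control or the Homo CDAHFD library. Of 159 named genes that were called, 146 kept their call with each library left out. Baz2b, at 0.24 (adjusted p = 0.560), was not called and ran from -0.12 to 0.68 as each library was left out.

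**Figure D4:**
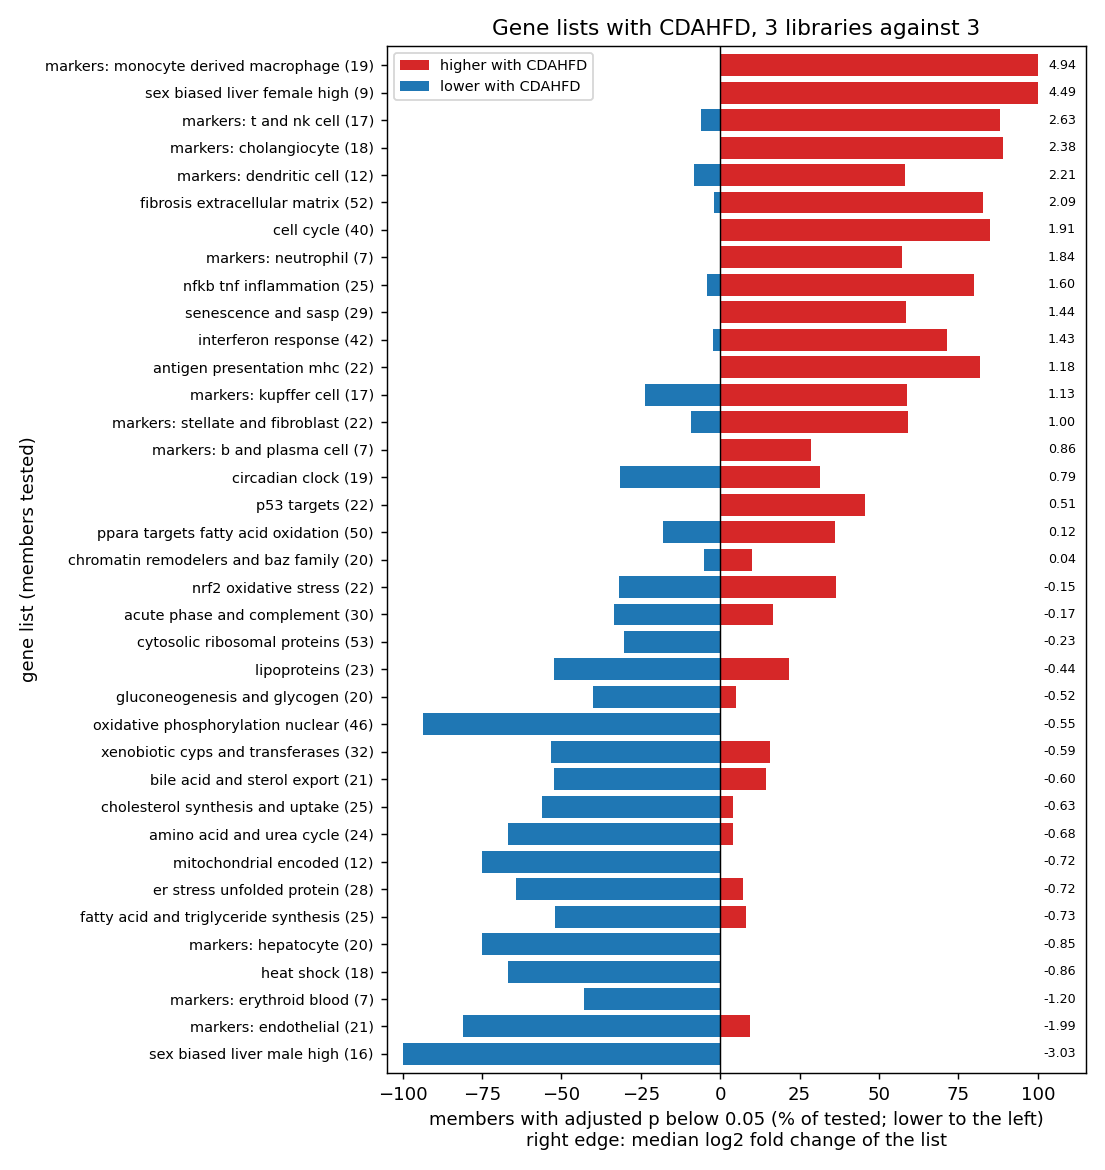
Percent of tested members called higher or lower in CDAHFD than in control livers for each gene list, by edgeR at adjusted p under 0.05, with the list's median log2 fold change at the right edge. Macrophage markers (19 of 19 higher) and male-high genes (16 of 16 lower) lie at the ends.

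Genotype in the diet cohort, averaged over both diets, changed no gene by edgeR. For the libraries labelled Homo against WT 0 of 12458 genes were called (446 at an unadjusted p under 0.05, and 9 by DESeq2). For Heter against WT it was 0 (202 at an unadjusted p under 0.05, and 3 by DESeq2). For Homo the count was 51 without the Homo CDAHFD library, 19 without the Homo control library and 3 without the WT CDAHFD library, and for Heter it was 5 without the Homo control library. Interferon response genes were lower in Homo as a list, with 41 of 42 log2 fold changes below 0 and a median of -0.55 (0 called, 7 lower adjusted over the list alone, camera adjusted p = 2.2e-10, adjusted p = 0.881 with an estimated correlation). Between single libraries the median was -0.98 under CDAHFD and 0.06 under the control diet (22 above and 20 below 0, percentile 82.5 of random lists). Fibrosis and extracellular matrix genes had a median of -0.19 (0 called, 0 adjusted over the list alone, camera adjusted p = 0.0015, adjusted p = 0.881 with an estimated correlation). Between single libraries this was -0.47 under the control diet (43 of 52 below 0, percentile 0, and -0.86 with 0.1 CPM added) and 0.08 under CDAHFD (35 of 52 above 0, percentile 97.0). In that control pair cholangiocyte (-0.40, percentile 0, and -0.89 with 0.1 CPM added), stellate (-0.19, 0.58), endothelial (-0.17, 2.43) and erythroid (-0.36, 0.49) markers were lower too. Kupffer cell markers were higher (0.29, 99.96). In Heter, cholangiocyte markers had a median of -1.03, with 18 of 18 below 0 (1 lower adjusted over the list alone, camera adjusted p = 1.6e-09, adjusted p = 0.902 with an estimated correlation). Of single genes, Nr1d1, a clock repressor, had -1.73 ± 0.16 in Homo (adjusted p = 0.0961).

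Differences between single libraries under 1 diet have no replicate check and compare those libraries. Homo and Heter are each set against the same WT library of a diet. Agreement between them may come from that library, and the rule for named genes itself asks for the same sign in Heter. In Homo against WT, 14 of 37 list medians lay below and 7 above the middle 95% of their random lists under CDAHFD, and 15 and 4 under the control diet. In Heter against WT these numbers were 11 and 5 under CDAHFD, and 8 and 9 under the control diet. So many lists lay outside because random lists do not copy how members of a list vary together, or because the livers differed. The percentiles cannot tell these apart. Interferon-induced genes were lower in the Homo CDAHFD than in the WT CDAHFD library. Isg15, a ubiquitin-like interferon product, had a log2 ratio of -2.32 with 1 CPM added, at 59.0 CPM in the WT and 26.0 in the Heter library. Ifit3 and Ifit1, which bind viral RNA, had -1.93 and -1.87. The interferon list's median log2 ratio was -0.98, below all of 10000 random lists matched on expression (percentile 0), and in Heter CDAHFD it was -0.29. PPAR alpha targets had a median of 0.42 (percentile 100) in Homo CDAHFD and 0.35 in Heter CDAHFD against WT CDAHFD. Markers of neutrophils (-0.38, percentile 0.83), Kupffer cells (-0.17, 1.48) and T and NK cells (-0.21, 1.90) were lower in Homo CDAHFD as well. With 0.1 CPM added these medians were -0.72, -0.26 and -0.40. Hepatocyte (0.17, 98.3) and cholangiocyte markers (0.22, 99.6) were higher. In Heter CDAHFD, markers of macrophages (-0.20, percentile 0), Kupffer cells (-0.17, 0.305), neutrophils (-0.36, 1.23) and cholangiocytes (-0.84, 0) were lower. Fibrosis and extracellular matrix genes had -0.20 there (38 of 52 below 0, percentile 0). In Heter against WT under the control diet they had 0.08 (32 of 52 above 0, percentile 95.4). A different mix of cells stays open for Homo CDAHFD and for Heter CDAHFD. G6pc stood at 345 CPM in Homo CDAHFD against 57.0 in WT, and Igfbp1, an insulin-repressed binding protein, at 320 against 55.7. Under the control diet, clock genes had a median of -0.68 and fatty acid and triglyceride synthesis -0.57 in Homo against WT (percentile 0 for both). In Heter against WT these were -0.38 (percentile 0) and -0.05 (7.25). Rgs16, a regulator of G protein signalling, stood at 2.46 against 220 CPM, and at 43.2 CPM in Heter. Dbp, a clock output gene, had -3.14, and -3.26 in Heter. Saa2, an acute phase protein, stood at 442 against 27.7 CPM, and at 470 CPM in Heter. For Dbp and Saa2 the WT control library thus lay apart from both others. The hour of sampling is not given in the labels.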

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

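Of the tests in this part, those of Y-linked genes, hepatocyte share, fasting, scaling and non-hepatocyte cells were chosen only after the result was seen, as were the fits over the 3 genotypes or both ages and the list medians with a library left out.

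Male-high liver genes were lower and female-high genes higher in elder than in young livers, with medians of -1.66 and 3.00 in the fit of age over the 3 genotypes (adjusted p = 0.391 and 0.487 with an estimated correlation). Female animals among the elder libraries would lower Y-linked genes as far, and their median log2 fold change was -0.15. A lower share of hepatocytes would lower their markers as far, and these had a median of -0.12. Reads shared within the Mup and Cyp families would leave other members level, yet the 8 male-high genes outside both families had a median of -1.66. A change with age in the hormone-driven sex pattern of the liver stays open as an untested hypothesis, as do differences in housing or strain that the labels do not give.

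Lipid synthesis genes were lower in WT elder than in WT young livers, and this age change differed from that in Homo (0.92) and in Heter (0.76) at the preset correlation only, with adjusted p = 0.513, 0.599 and 0.441 with an estimated one. Among elder livers alone Homo differed from WT by only 0.15 (lost without WT elder 2 or either Homo elder library) and Heter by 0.49, and among young livers Homo differed by -0.71, so the young libraries make most of the difference for Homo. Fasting of the WT elder animals would raise G6pc, Pck1 and Tat, whose median log2 fold change was -2.30. A single WT library does not set the difference, since the highest median with 1 library left out was -0.61, and with median-of-ratios scaling the median was -0.70. The age of the animals, and differences in feeding or time of day other than fasting that would move G6pc and Scd1 together, may each account for it and cannot be separated by these labels.

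Endothelial markers were lower in the libraries labelled Homo than in WT among elder livers at the preset correlation (adjusted p = 0.716 with an estimated one). The genotype is given as labelled, since Baz2b counts over the whole gene cannot check it. An equal fall of all non-hepatocyte cells would lower each of their lists as far, yet T and NK cells had 0.38 (0.08 to 0.84 as each library was left out), Kupffer cells -0.01 (-0.30 to 0.33), stellate cells -0.02 (-0.28 to 0.15) and macrophages 0.07 (-0.25 to 0.22), against -0.53 to -0.40 for endothelial markers. Lists of B and plasma cells (-0.31), cholangiocytes (-0.33), dendritic cells (-0.22), neutrophils (-0.25) and mesothelial cells (-0.55) had medians below 0, so a lower share of several cell types stays open. One library does not set it, since the highest median with 1 elder library left out was -0.40. A lower share of endothelial cells, lower expression per cell and an effect of the genotype stay open, since the 95.2% of 21 markers with a negative log2 fold change only restates the pattern.

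Other splits of the libraries were fitted as a check on chance. For age over the 3 genotypes 100 of 462 possible splits of the 12 libraries were run, and only the real one gave as many genes (2348, highest other 599). So large a count was thus rare among these splits. They treat libraries of a group as separate animals, which the labels do not state. Nor can they tell age from any other difference shared by the elder libraries. For Homo over both ages the real split called 0 genes. All 34 of 34 splits give as many by construction (highest other 7), so this comparison decides nothing about chance. For CDAHFD the 10 splits of 6 libraries are too few for a share under 0.05, with 5400 genes for the real split, 1 of the 10, and 0 for the highest other.

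The remaining results singled out are age changes that differed between genotypes by the test of the difference. Against WT, the libraries labelled Homo had median differences of 0.63 for amino acid and urea cycle genes, 0.51 for gluconeogenesis, -0.87 for ER stress, -0.39 for heat shock, -0.58 for endothelial markers and 2.12 for erythroid genes. As each library was left out, the amino acid, gluconeogenesis, ER stress, heat shock and erythroid medians ran from 0.35 to 0.79, 0.35 to 0.70, -1.15 to -0.38, -0.54 to -0.21 and 1.37 to 2.45. The calls of 6 lists were lost with 1 library left out. These were bile acids (0.25, without WT young 2, Homo young 2 or Homo elder 2, highest adjusted p 0.23), oxidative phosphorylation (0.17, without Homo young 2, WT elder 1 or Homo elder 2, 0.33), xenobiotic metabolism (0.20, without those 3 or WT young 2, 0.92, turning without WT elder 1) and clock genes (0.26, without library 2 of any group, 0.66). Antigen presentation (0.10, highest 0.34) was lost without any library but WT young 1, WT elder 2 or Homo elder 1, and hepatocyte markers (0.15, 0.60) without any but WT elder 2 or Homo elder 1. In Heter the differences were 0.47 for amino acid and urea cycle genes, 0.56 for gluconeogenesis, -0.75 for interferon genes, 0.30 for hepatocyte markers and 1.49 for erythroid genes. In that order their medians ran from 0.31 to 0.64, 0.27 to 0.72, -0.98 to -0.47, 0.22 to 0.45 and 1.01 to 2.08. The calls of 7 further lists were lost with 1 library left out. These were cholesterol synthesis (0.43, without WT elder 2 or Heter elder 1, highest adjusted p 0.83), bile acids (0.24, without Heter young 1 or Heter elder 1, 0.06), ribosomal proteins (0.19, without Heter young 1, 0.18) and macrophage markers (-0.60, without Heter elder 1, 0.057). Antigen presentation (-0.18, 0.60) was lost without WT young 1, Heter young 1, WT elder 2 or Heter elder 2. Cholangiocyte markers (-0.24, 0.74) were lost without any library but WT young 2 or Heter elder 1, and NF-kB and TNF targets (-0.25, 0.50) without any but WT young 2. None of these lists was called with an estimated correlation (smallest adjusted p 0.599 for Homo and 0.441 for Heter). Of single genes, Ugt1a5 had 3.47 in Heter, and the age change of Baz2b in Homo differed by -0.50 (unadjusted p = 0.0196, adjusted p = 0.733 by edgeR).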

How the results depend on the processing

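Of the alternatives in this part, the fits of age over the 3 genotypes and of Homo over both ages, the correlations and list medians with a library left out, and the filter by the compared factor were chosen only after the result was seen. Counts of changed genes with 2 libraries per group depended most on which library was left out and on the tool. Fits with a library left out also ran the expression filter again, so the genes tested could differ. No named gene that was called turned its direction with a library left out. Those named for a large fold change had groups that do not overlap, so they could hardly turn. Of values not called, 27 in the ageing cohort and 1 in the diet cohort turned. With median-of-ratios size factors in edgeR all 14 counts of genes stayed within 1.5 times of their value. Apart from a different number of libraries or tested genes where an alternative itself brings it, the cause was not tested.

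DESeq2 called 781 genes with age in WT, 384 in Heter and 860 in Homo, 48 in Homo elder, 38 in Heter elder, 7 in Homo young, 18 and 32 for the difference of the age change in Homo and Heter, 9 and 3 for Homo and Heter in the diet cohort, and 28 for Homo over both ages (0 in edgeR). With no expression filter 210 genes changed with age in Heter, and there were 2 in Homo elder, 8 in Heter elder, 2 in Homo young, 2 for the difference in Heter, 2 and 1 for Homo and Heter in the diet cohort, and 5 for Homo over both ages. With only the groups compared in the fit they were 146 with age in Heter, 7 in Homo elder, 11 in Heter elder, 2 for the difference in Homo and 4 for that in Heter.

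The replicate number as a block gave 0 genes in Heter young, 0 for the difference in Heter and 1 for Homo over both ages, and moved no other of 11 counts by over 1.5 times. Libraries with the same number did not deviate together (15 correlations between group pairs from -0.143 to 0.112, 1 above 0.1 and 3 below -0.1), so the numbers do not pair the libraries. No list was called with an estimated correlation, 0 in each of the 12 comparisons, so 175 list calls were lost and 287 results stayed on their side of the threshold.

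With each library left out, counts ran from 63 to 227 with age in WT, 26 to 62 in Heter and 85 to 171 in Homo, 0 to 49 in Homo elder (49 without WT elder library 2), 0 to 5 in Heter elder, 0 to 1 in Heter young, 0 to 30 for the difference in Homo, 0 to 5 for that in Heter, 0 to 51 for Homo and 0 to 5 for Heter in the diet cohort, and 0 to 2 for Homo over both ages. Between 3312 and 5391 genes changed with CDAHFD, while counts of genes changed with age over the 3 genotypes ran from 1586 to 2310 (2265 with a filter by the compared factor). Of the 424 genes called with age in WT, 56, 135, 124 and 155 were called again without young library 1, young library 2, elder library 1 and elder library 2.

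Correlations across genes with mean CPM of at least 10 were -0.0984 for age in Heter against Homo elder, -0.0362 for Homo young against Homo elder (reversed from 0.0560), 0.655, 0.684 and 0.654 for age in WT against Heter, WT against Homo and Heter against Homo. With each library left out, r ran from -0.0782 to -0.00995 for age in Heter against Homo elder. It ran from -0.0328 to 0.0605 for Homo young against Homo elder. For age in WT it ran from -0.570 to -0.258 against Homo elder and from -0.577 to -0.244 against Heter elder. Homo elder against Heter elder gave 0.322 to 0.675. Between age changes, WT against Heter gave 0.407 to 0.477, WT against Homo 0.411 to 0.536 and Heter against Homo 0.383 to 0.477. With all libraries these pairs of age changes had 0.562, 0.616 and 0.558, each above its range. The fits with a library left out could test other genes, so these ranges are not those of the same gene set.

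Of named genes, DESeq2 moved 89 past the threshold and 6 below it and left 872 on their side, and the fit without a filter moved 19 and 11 and left 1031. The block moved 3 past it and 22 below, and median-of-ratios scaling 1 below. List tests of the diet cohort were not repeated with a library left out. A pseudocount of 0.1 CPM moved 4 of 74 single-library list medians and 0 of 40 genes, and scaling by total counts 6 of 40 genes.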

Other observations

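The alternatives in this part were planned, and its genes were picked from those the rule names after their values were seen.

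Senescence and clock genes held single changes in the libraries labelled Homo with age, while neither list was called as a whole (medians 0.19 and 0.22). The single genes given here thus do not show more senescence. Cdkn2a, an inhibitor of the cell cycle that marks senescent cells, was at least 8.81-fold higher in elder than in young Homo livers, against a floor of 3 counts over the group, a call lost without any 1 of the 4 libraries (highest adjusted p 0.169). Lmnb1, a nuclear lamin, rose by a log2 fold change of 1.17 and Per3, a clock gene, by 1.38, and both calls were lost in the same way (0.120 and 0.155). Whether these changes differ from those in WT was not shown, as 0 genes had a different age change in Homo by edgeR (802 at an unadjusted p under 0.05, and 18 by DESeq2).

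Under CDAHFD the oxidative stress and clock lists held members that moved far apart. Hmox1, which breaks down heme, had a log2 fold change of 2.98 and Slc7a11, a cystine carrier, was at least 54.5-fold higher, while Cat, the catalase, had -1.35. Of clock genes Arntl, an activator, had -3.16 and Usp2, a ubiquitin protease with a daily rhythm, 2.92, and the hour of sampling is not given in the labels. Csf1r and C1qc, both made by Kupffer cells and other macrophages, had 2.99 and 2.96. Among female-high genes Cyp2b9 had 6.26 (5.86 to 6.93 as each library was left out), and among male-high genes Cyp7b1, which hydroxylates oxysterols, had -3.72.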
